A study of Mus musculus with 5 samples.

How the data were processed

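Gene expression was profiled on 5 arrays of biotin-labelled RNA from mouse ES cells with an inducible Satb1 transgene. The deposited table holds log2 values for 35557 probe sets, summarised by the authors with RMA (background correction, normalization between arrays and a summary of each probe set), per the submitters' processing notes, in which no version is given. The software and the grouping of probes are not given in the sources used here. Scale was read from the values, which ran from 0.79 to 13.1. Sorted values of the arrays nearly coincided, so a shift of all transcripts in 1 group would not be seen.

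The deposited values held many exact ties between arrays within a probe set, a feature of summaries based on medians. Only 1800 of 19938 genes (9.03%) had 5 distinct values, 15.1% had the same value on all arrays, and 28.9% had the same value on all 3 induced arrays. Equality was taken as exact, with no tolerance. Ties make the spread within a group too small. The prior SD that limma estimated was 0.0050 over all genes and 0.086 over the genes with 5 distinct values, with prior degrees of freedom of 0.467 and 2.87. The design fixed beforehand was kept for the reported counts, and 2 settings were added after seeing the data. The first took limma's prior from genes with 5 distinct values and applied it to every gene, and the second tested only the 3899 genes untied within both groups.

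Probe sets were named through the array's annotation table, where 21789 had 1 gene symbol and 1621 had several. A further 12147 were not listed and are unnamed here. Of those with 1 symbol, 21698 matched the gene table of assembly GRCm38.p6 by gene identifier and 91 did not, and no symbol changed. No coordinates are given because the sources used here name no build. The probe set with the highest mean over all 5 arrays stood for a gene, which gave 19938 genes, 999 of them with several probe sets. No filter on low values was used. The 13768 probe sets without a single name were tested separately.

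Groups came from the sample titles, with 2 uninduced and 3 induced arrays. Genes were tested with limma 3.58.1 (lmFit and eBayes without trend) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. With 5 arrays there are 10 splits into 2 and 3, so an exact permutation test of a single gene cannot give a p under 0.1 and was not used. Lists of genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists, all of which had at least 5 measured members. Camera with an estimated correlation and fry were alternatives.

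Designs, gene lists, the named genes and most alternatives were fixed before the data were examined. Named genes were Satb1, Nanog, Klf4, Tbx3, Pou5f1 and Sox2 whatever their result, then 12 genes per direction. These were the genes past the threshold whose induced arrays all lay on the same side of both uninduced arrays, by size of change, filled up with the smallest p in that direction. Up to 4 members with the smallest p were named from each list described.

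Alternatives were the mean of all probe sets of a gene, genes above the median level, arrays centred on their medians, quantile normalization applied again, eBayes with trend and robust, the title number as a block, the feeder mean as a covariate, and each array left out. A 1.5-fold minimum, an adjusted p threshold of 0.01, camera on ranks and lists without Satb1 were also tried. RNA quality was not analysed here, because the 3-prime and 5-prime control probe sets named in the plan could not be told from other probe sets. The plan to leave out probe sets with names ending in x_at or s_at did not apply to the numeric names of this array.

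The tests were tested on simulated data for the induced against uninduced comparison, with the means of the 19938 genes and the spread of genes with 5 distinct values. Without ties, limma recovered 89 of 100 genes changed by 1 on the log2 scale and 28 of 100 changed by 0.5, with 7 false calls among 19738 unchanged genes. With the tie pattern of the real arrays, it recovered 78 and 61 and made 104 false calls. With the prior from genes with 5 distinct values on the same tied data it recovered 94 and 68 and made 19 false calls. Lists were simulated in 20 draws of 30 lists of 20 independent genes, 1 of them shifted by -0.25. With ties, the shifted list was called in 20 draws by camera with the preset correlation, in 15 with an estimated correlation and in 20 by fry, and 0, 0 and 15 of 580 unshifted lists were called. Without ties, these draws numbered 20, 2 and 17, with 1, 0 and 1 unshifted lists called. Real genes of a list can move together, which these draws leave out.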

Results

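RNA was measured on 5 microarrays from mouse embryonic stem (ES) cells, the self-renewing cells of the early embryo kept in culture with the cytokine LIF, that carried a Satb1 transgene under a doxycycline-inducible (tetO) promoter. Satb1 encodes a nuclear protein that binds AT-rich DNA and is best known from developing T lymphocytes. The uninduced group had 2 arrays and the induced group had 3 arrays of cells given doxycycline (DOX) for 24 h. RNA was taken 48 h after passaging in both groups, and the comparison asks which transcripts differ when Satb1 is overexpressed. The labels do not say whether arrays of a group came from separate cultures. The p-value of a gene therefore measures the spread between these arrays, which may be technical. For gene lists, camera with the preset correlation of 0.01 compares list members with all other genes. Its p-values do not measure the spread between arrays or cultures. The design had no DOX-treated cells without the transgene, so each difference is one between DOX-treated and untreated cells. The number of arrays limits the precision of every value.

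The arrays were close to each other. Across 19938 genes, Pearson's r between pairs of arrays lay between 0.9972 and 0.9979, and genes are not independent replicates. Array medians lay between 4.91 and 4.92 on the log2 scale. Between 40.6% and 44.6% of genes had exactly the same value on a given pair of arrays, and no pair was the same throughout. The labels differ on feeder cells: the treatment protocol names irradiated feeders, which the extraction protocol reduces by settling, while the design text of the series speaks of culture in LIF only. The mean level of 24 measured fibroblast genes, such as the collagens Col1a1 and Col3a1, was 5.474 and 5.477 on the uninduced arrays and 5.478, 5.498 and 5.495 on the induced arrays, so that each induced array lay above both uninduced arrays by a small amount. The fibroblast list had a median log2 change of 0.0039 and no call (adjusted p = 0.966, limma's camera).

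Satb1 itself was 11.7-fold higher in induced cells. Its probe set, 10451763, had a log2 level of 5.14 ± 0.28 (SD, n = 2) in uninduced and 8.69 ± 0.09 (SD, n = 3) in induced cells, a difference of 3.55 with a standard error of 0.15. All 3 induced arrays, at 8.61, 8.79 and 8.68, lay above both uninduced arrays, at 4.95 and 5.34. No other gene had an increase of 1.5-fold or more. In limma over all genes Satb1 had an adjusted p of 0.229 and did not pass 0.05. With the spread estimated from the 1800 genes that had 5 distinct values, a setting chosen after seeing the data, its adjusted p was 0.0038 with a 95% interval of 3.23 to 3.86, and with only the untied genes tested it was 0.00053. Without uninduced array 1 or 2 it was 0.0042 or 0.0034, in fits with a single uninduced array that called 1980 and 1979 genes, and without induced array 1, 2 or 3 it was 0.663, 0.637 or 0.656.

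**Figure D1:**
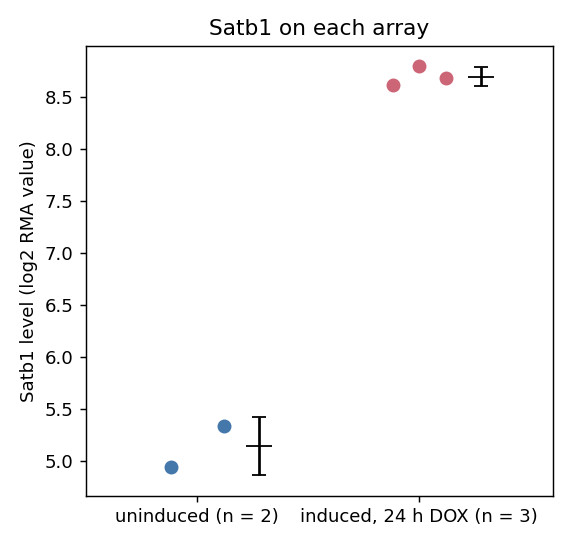
Satb1 on each array, as log2 RMA values (vertical axis), for 2 uninduced arrays and 3 arrays of cells given DOX for 24 h; points are arrays and the black marks are group means with their SD. The induced arrays lay between 8.61 and 8.79 and the uninduced arrays at 4.95 and 5.34.

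The 3 genes that passed the test over all genes, Satb1 not among them, changed little. Prmt8, which encodes a membrane-bound arginine methyltransferase, was lower by a log2 change of -0.30 (adjusted p = 0.0011, limma). Gpr55, a G protein-coupled receptor gene, and Gm4759 were higher by 0.19 and 0.10 (adjusted p = 0.016 for both). Thus 2 genes were higher and 1 was lower among 19938, with 96 higher and 213 lower at an unadjusted p under 0.05. Each of the 3 genes had 1 identical value on all 3 induced arrays. With the spread from genes with 5 distinct values, none of them passed (adjusted p = 1 for each), Satb1 was the 1 higher gene, and the count of lower genes was 0, with 60 higher and 154 lower at an unadjusted p under 0.05.

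Among genes above the median level, 4 were lower by 1.5-fold or more. These were Egln3, a HIF prolyl hydroxylase gene, at -0.90 ± 0.13 (standard error of the log2 change), Bnip3, a mitophagy receptor gene, at -0.88 ± 0.17, the junctional adhesion molecule gene Jam2 at -0.79 ± 0.10, and the zinc finger gene Sall1 at -0.66 ± 0.03. Bnip3 and Jam2 were named after their values were seen. None passed over all genes (adjusted p = 0.770 for the first 3 and 0.230 for Sall1). Sall1 had a log2 level of 7.77 ± 0.04 (SD, n = 2) in uninduced and 7.11 ± 0.04 (SD, n = 3) in induced cells. It passed when only the 3899 genes untied within both groups were tested, a setting chosen after seeing the data (adjusted p = 0.041), and in the fits with a single uninduced array, which called 1980 and 1979 genes (0.016 without array 1 and 0.019 without array 2). It did not pass without induced array 1, 2 or 3 (adjusted p = 0.585, 0.647 and 0.656), and it did not pass with the spread from genes with 5 distinct values (adjusted p = 0.371).

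The 12 lower genes named by rule were Prmt8 and 11 that did not pass. Of these, Tpi1, which encodes the glycolytic enzyme triosephosphate isomerase, had a log2 change of -0.31, and the predicted ubiquitin ligase gene G2e3 had -0.24. Lef1, a transcription factor gene of the WNT pathway, the mitotic survival gene Birc5, Leng8 and Fthl17f each had -0.13. H2bu1-ps, Fbxw2, Ext1 and Zfp40 had smaller changes, down to -0.06 in Zfp40, and Sall1 is described above. The 12 higher genes were Gpr55, Gm4759, Satb1 and 9 that did not pass, namely Chgb, Lce1a2, Dkk4, Trbv1, Tspan9, Atp8a1, Aadacl4fm1, Hpcal1 and Btbd2. Apart from Satb1, the largest change among these 12 was the 0.19 of Gpr55. All induced values lay below all uninduced values in 615 genes (3.08%) and above them in 329 genes (1.65%), where chance gives 10% per direction without ties.

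The number of genes passing depended on single arrays. Without uninduced array 1, 883 genes were higher and 1097 lower, and without uninduced array 2 these counts were 1051 and 928, with the lone array assumed to vary like the induced ones. Without induced array 1, 2 or 3, the counts were 1 and 1, 0 and 1, and 0 and 0, and centring each array on its median, by itself, gave 0 in both directions.

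Genes of the hypoxia response and of glycolysis were lower in induced cells. Of 20 measured members of this list, 19 had a lower mean, Car9 had the same value on all arrays, and none was higher. The median log2 change was -0.24, which is 1.18-fold lower (camera adjusted p = 5.9e-18 over 30 lists). With the correlation between genes estimated from the arrays, at 0.149 against the preset 0.01, the call was lost (camera adjusted p = 0.339). No member passed over all genes, and 9 fell when adjusted over the list alone (limma), namely P4ha1, Egln3, Ddit4, Aldoa, Ero1a, Ndrg1, Bnip3, Adm and Egln1. P4ha1, a collagen prolyl hydroxylase gene, had a log2 change of -0.48 ± 0.04 (standard error), and its adjusted p over the list alone was 0.014. Ddit4, an inhibitor of mTORC1 signalling, had -0.50 ± 0.08, and the glycolytic aldolase gene Aldoa had -0.22 ± 0.03. A second probe set of Bnip3 had -0.50, and 3 probe sets of Pgk1, 2 of them with the same values, had -0.29, -0.29 and -0.30.

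In 15 of the 20 genes every induced array lay below both uninduced arrays. The mean of the list was 7.61 and 7.58 on the uninduced arrays and 7.34, 7.25 and 7.27 on the induced arrays. Vegfa, at -0.12, and Pdk1, at -0.04, did not pass over the list alone. The feeder mean, given above, was slightly higher on the arrays where this list was lower. With the feeder mean as a covariate the median log2 change was -0.15, over 1.5 times smaller, and the call was kept (adjusted p = 5.7e-07). The median lay between -0.29 and -0.22 with any array left out.

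**Figure D2:**
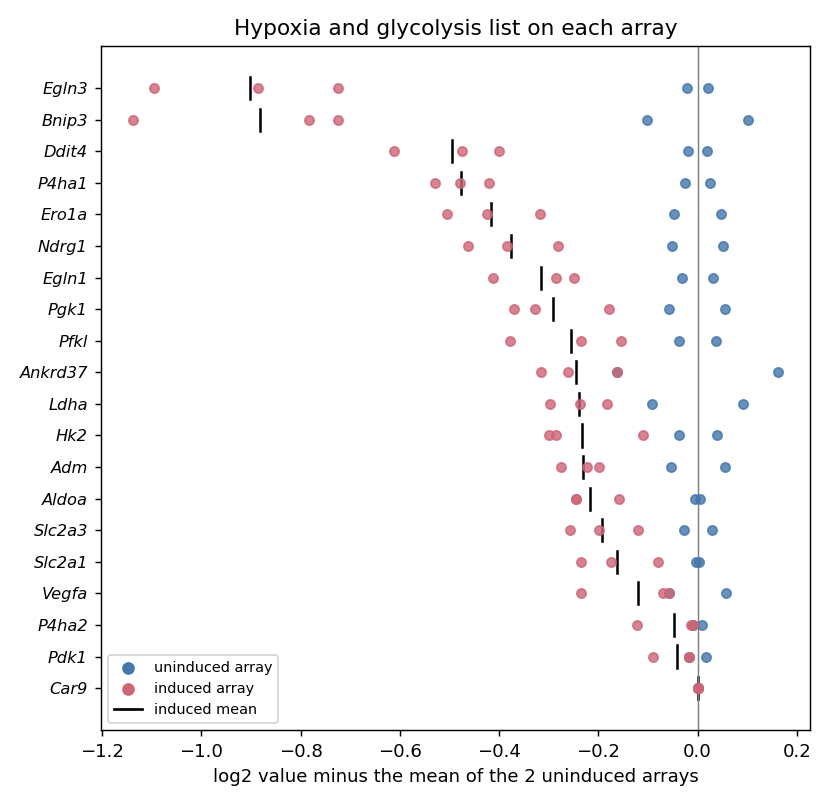
Levels of the 20 measured hypoxia and glycolysis genes on each array, as the log2 value minus the mean of the 2 uninduced arrays (horizontal axis); blue points are uninduced arrays, red points induced arrays, and black bars induced means. In 15 genes all 3 induced points lie below both uninduced points, and Egln3 and Bnip3 have the lowest means, at -0.90 and -0.88.

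Genes of the naive pluripotent state, the transcription factors and markers that set ES cells apart from later epiblast, were slightly lower in induced cells as a list. Of 18 members, 16 had a lower mean, 1 a higher mean and 1, Esrrb, the same value on all arrays. The median log2 change was -0.05 (camera adjusted p = 9.8e-05), and with an estimated correlation the call was lost (adjusted p = 0.339). No member passed over all genes or adjusted over the list alone. The members with the smallest p were Nr5a2, an orphan nuclear receptor gene, at -0.27 ± 0.05 (standard error), the methylcytosine dioxygenase gene Tet2 at -0.37 ± 0.09, Nr0b1 at -0.25 ± 0.08 and Klf4 at -0.35 ± 0.19. The other genes named beforehand were Nanog, at -0.06 ± 0.04, and Tbx3, at -0.11 ± 0.14. Nanog was at -0.10 without uninduced array 1 and at -0.01 without uninduced array 2. Tbx3 had the same value, 5.62, on all arrays except induced array 2, at 5.28, and without that array its change was 0. Klf4 was at 6.93 ± 0.02 (SD, n = 2) in uninduced and 6.58 ± 0.27 (SD, n = 3) in induced cells, so the induced arrays differed among themselves by an amount near that of the change. The mean of the list was 7.21 and 7.24 on the uninduced arrays and 7.14, 7.09 and 7.12 on the induced arrays. Without uninduced array 2, in a fit with a lone uninduced array, the list did not pass, at a median of -0.036. Nor did it pass with the feeder mean, higher on all induced arrays, as a covariate (camera adjusted p = 0.269).

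General pluripotency genes gave no call. Of 15 members, 11 had a lower and 4 a higher mean, with a median of -0.0032 (adjusted p = 0.747). Pou5f1, the gene of the core pluripotency factor OCT4, was at 9.89 ± 0.05 (SD, n = 2) in uninduced and 9.94 ± 0.02 (SD, n = 3) in induced cells. Sox2 was at 9.93 ± 0.07 and 9.92 ± 0.02 in the same groups, and neither passed the test.

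Genes of the G2 and M phases of the cell cycle were lower as a list by a small amount. Of 19 members, 15 had a lower and 4 a higher mean, and the median log2 change was -0.03 (camera adjusted p = 0.011). With an estimated correlation the call was lost (adjusted p = 0.696). No member passed over all genes or adjusted over the list alone. The kinesin gene Kif11 had -0.05 ± 0.02 (standard error), the spindle gene Nusap1 -0.13 ± 0.06, the hyaluronan receptor gene Hmmr -0.10 ± 0.05 and the proliferation marker Mki67 -0.08 ± 0.04. The call was lost without uninduced array 2 (adjusted p = 0.722), without induced array 3 (adjusted p = 0.112), and with the feeder mean, higher on all induced arrays, as a covariate (adjusted p = 0.756). It was also lost among genes above the median level (adjusted p = 0.066), with quantile normalization applied again (0.287) and with the spread from genes with 5 distinct values (0.084) or only untied genes (0.376). Genes of S phase had no call (adjusted p = 0.638).

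None of the other 27 lists passed, and no list was higher (camera adjusted p from 0.197 to 0.986 over these 27). Lineage markers had adjusted p-values of 0.246 for primitive streak and mesendoderm, 0.299 for trophectoderm, 0.434 for primed epiblast, 0.638 for primitive endoderm and 0.966 for neuroectoderm and for blood and endothelium. The lymphoid list, which holds genes tied to Satb1 in T cells such as Il2ra and Bcl6, had a median of 0 and an adjusted p of 0.986. Chromatin partners of SATB1 and WNT response genes each had 0.299, Polycomb and DNA methylation genes 0.197, LIF and STAT3 response and cholesterol synthesis genes each 0.246, and the SATB and CUX homeobox family 0.480. The p53 response had 0.299, Y-linked genes 0.434, germline genes 0.458 and imprinted genes 0.483. BMP and SMAD response, 2-cell-like, mitochondrial unfolded protein, interferon and MHC class I, and integrated stress response genes each had 0.638. Hox genes and ERK feedback genes each had 0.966.

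**Figure D3:**
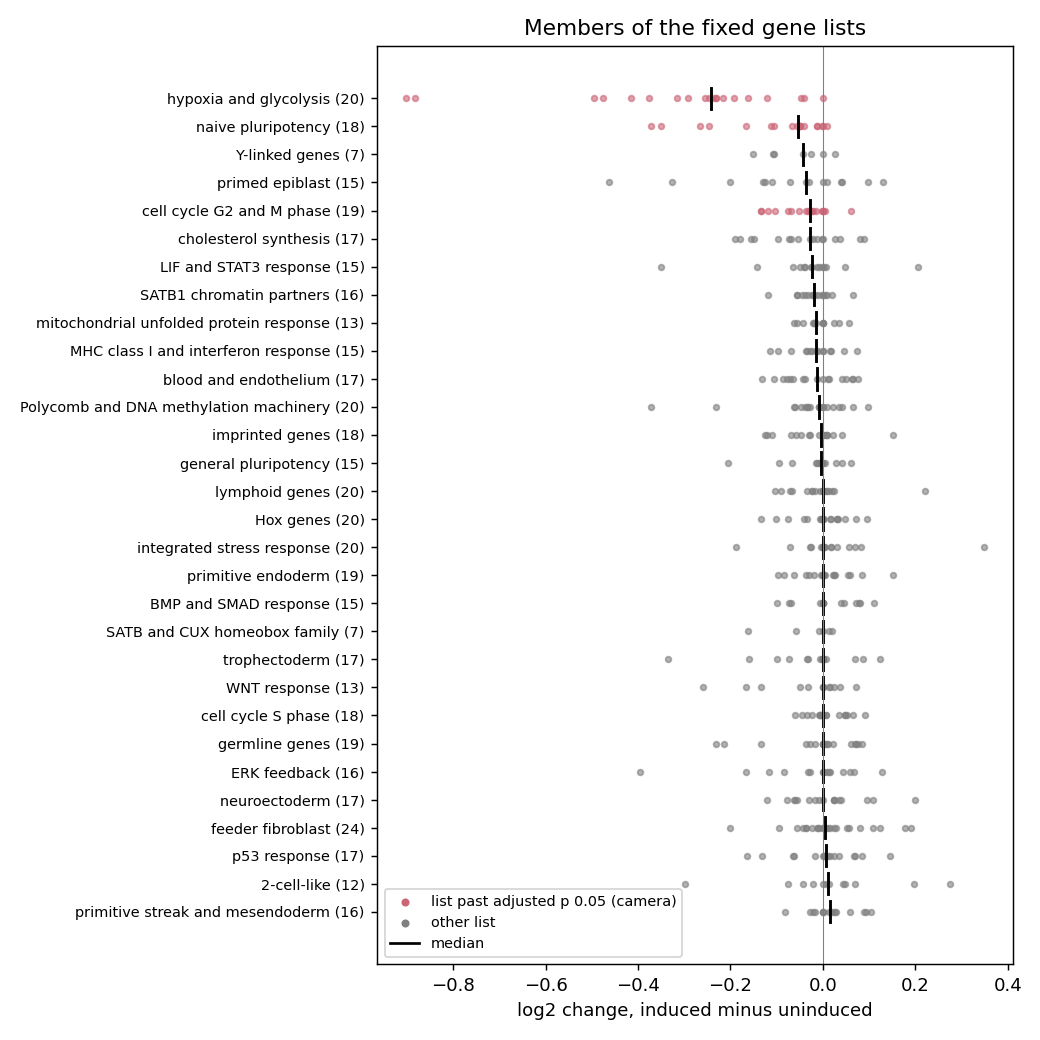
Log2 change, induced minus uninduced (horizontal axis), of the measured members of the 30 gene lists, with the number of members in parentheses; each point is a gene, black bars are medians, and lists past an adjusted p of 0.05 in camera are red. Satb1, at 3.55 in the SATB and CUX family, lies outside the axis; the hypoxia and glycolysis list has a median of -0.24.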

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

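Probe set 10344292, which the annotation table does not name, was lower in induced arrays by a log2 change of -1.20 (limma adjusted p = 0.011 over the 13768 probe sets without a single gene name). It was picked out because it lies outside the named genes that the comparisons use. Its level was 3.18 and 3.19 on the uninduced arrays and 2.00, 1.99 and 1.97 on the induced arrays. With the spread from probe sets with 5 distinct values, a setting chosen after seeing the data, it did not pass (adjusted p = 1). Other unnamed probe sets at low levels had larger changes in both directions that did not pass, such as 10343655 at 1.54 and 10342995 at -1.89.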

How the results depend on the processing

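Tests with the spread from genes with 5 distinct values and with only untied genes were chosen after seeing the data; the others were planned. The Satb1 change kept its direction in all 14 alternatives, at 3.35 to 3.75 with single arrays left out (adjusted p from 0.00053 to 0.693 over the alternatives), and it newly passed, at 3.55, with the spread from genes with 5 distinct values and with only untied genes. Against 2 higher and 1 lower genes, both counts were 0 for genes above the median level, centred arrays, quantile normalization applied again, the feeder mean as a covariate and a 1.5-fold minimum; an adjusted p threshold of 0.01 left 0 higher. The shared spread gave 1 higher and 0 lower, and untied genes gave 1 higher. With single arrays left out, the higher count ran from 0 to 1051 and the lower count from 0 to 1097. A lone uninduced array leaves the spread to the induced arrays, whose ties make it small. Centring moved each array by a constant and thereby broke the ties. Prmt8, Gpr55 and Gm4759 lay below the median level of 5.06, so the setting of genes above it left them out. Their changes were also smaller than 1.5-fold. The cause of the remaining changes was not tested.

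Against 3 lower lists, there were 0 with an estimated correlation, 0 with fry, 1 with the feeder covariate and 1 to 5 with single arrays left out. The hypoxia and glycolysis list kept its call in 15 of 17 alternatives and lost it, at -0.24, with an estimated correlation (adjusted p = 0.339) and fry (0.094); with the feeder covariate it kept the call at -0.15. Most alternatives that kept the call used camera at the preset correlation of 0.01, so they are not independent support for it. The estimated correlation of this list was 0.149. Of the 20 measured members of the list, 5 had a tie. In simulated data of independent genes, the estimated correlation called a planted list in 15 of 20 draws with ties and in 2 of 20 without ties. Those draws cannot discount a correlation between real members of the list. The naive pluripotency list lost its call with those tests, at -0.053, and with the feeder covariate, at -0.047. It ran from -0.10 to -0.036 with single arrays left out and was at -0.14 with only untied genes. The G2 and M phase list lost its call at -0.029 with those tests, genes above the median level and the shared spread, at -0.026 with the feeder covariate, at -0.010 with quantile normalization and at -0.064 with untied genes. It ran from -0.058 to -0.0054 with single arrays left out, and the cause was not tested.

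Same-numbered arrays of the 2 groups were not shown to be paired. The correlations of their deviations from the group means were -0.0063 and 0.0063, and the title number is not explained in the labels. The fit with the number as a replicate block gave 0 higher and 0 lower genes, a Satb1 change of 3.56 and a G2 and M phase median of -0.031 without a call.

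Genes that did not pass changed sign at sizes within their spread. Sox2 was at 0.0024 with quantile normalization, 0.0048 with the block and without induced array 3, and 0.043 without uninduced array 2 (-0.052 without uninduced array 1), and Tbx3 was at 0.044 with the feeder covariate. Of the other values of named genes under the alternatives, 450 stayed on their side of the threshold without turning sign (Tbx3 was at 0 without induced array 2), 39 newly passed and 22 no longer passed. Leaving out probe sets by name suffix was not run. Low levels limit what can be seen: a gene near the floor of 0.79 has little room to fall, and signal over background was not given per probe set.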

Other observations

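Outside the fixed lists, the 6 genes with the smallest p not yet described, with the spread from genes with 5 distinct values, were Prelid2, Pfkp, Saa2, Scd2, Slc16a3 and Scd1. They were named after their values were seen, and none passed over all genes (adjusted p = 1). Pfkp, a phosphofructokinase gene, had a log2 change of -0.43, the lactate transporter gene Slc16a3 -0.45, Prelid2 -0.47 and the acute-phase gene Saa2 0.48. The fatty acid desaturase genes Scd1 and Scd2 had -0.33 and -0.38. In lists that were not called, Lef1 (-0.13) and the cyclin gene Ccnd2 (-0.26) passed adjusted over the WNT list alone, Fdps (-0.19) over the cholesterol synthesis list alone, Uhrf1 (-0.06) over the Polycomb and DNA methylation list alone and Lox (-0.20) over the fibroblast list alone (limma). With the spread from genes with 5 distinct values none of these 5 passed over its list.

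The test of ties, the use of the feeder median against feeder RNA and the question of DOX without the transgene were chosen after the results they bear on were seen; the fit with the feeder covariate and the other tests were chosen before. The first pattern was that 3 genes with changes under 0.3 passed while Satb1, at 3.55, did not. A candidate explanation is the exact ties in the deposited values. All 3 genes had tied induced values, and 0 of them passed with the spread from genes with 5 distinct values. That spread sets a smallest standard error of 0.055, with which no change under 0.3 could pass, tied or not. The loss of the 3 calls with that spread therefore cannot decide whether ties caused them. In limma over all genes, Prmt8 and Gm4759 had a standard error of 0.0017, which came from the prior alone. Car9, with the same value on all arrays, had the same standard error. With centred arrays, which broke the ties, the 3 changes were nearly the same. None then passed (adjusted p = 0.156 for Prmt8, 0.332 for Gpr55 and 0.857 for Gm4759, limma). The simulation with the real ties made 104 false calls among unchanged genes, against 7 without ties. Biological change in these 3 genes was not excluded. Prmt8 and Gm4759 had no spread in either group, and Gpr55 had 2 uninduced values that differed little (SD 0.0050). With tied values, so small a spread is no evidence of a reproducible change. All 3 genes lay below the median level of 5.06, at 4.17 and 2.52 on the induced arrays for Prmt8 and Gm4759 and 4.08 for Gpr55.

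In the second pattern, the lower hypoxia and glycolysis list, a chance choice of members was tested with another list of hypoxia-responsive genes. That list had no gene in common with the first and was written before its values were looked at. Of 22 measured genes 16 were lower, 4 higher and 2 equal, with a median of -0.06. Camera gave p = 0.0025 with the preset correlation and 0.055 with an estimated correlation, on either side of 0.05, so the question stays open. Without uninduced array 1 camera no longer placed this second list below other genes, but a fit with a lone uninduced array cannot decide the question. For feeder RNA, the feeder median was 0.0039, but 23 of the 24 feeder genes had tied values, which hold that median near 0. The feeder median alone therefore cannot exclude feeder RNA. With the feeder mean as a covariate the hypoxia and glycolysis list kept its call (camera adjusted p = 5.7e-07). The median of this list was then -0.15 in place of -0.24. A part that moves with the feeder mean, which was higher on every induced array, stays open. Whether Satb1, DOX itself or a difference in culture density or oxygen lowered these genes cannot be told apart, since the design has 0 arrays of DOX-treated cells without the transgene. Of the 10 splits of the arrays into 2 and 3, only 1, the real split, gave a median as large as its 0.24 (highest other, 0.22), and 10 splits are too few for a share under 0.05.

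The third pattern was the slightly lower naive pluripotency list. It does not rest on induced array 2 alone, as without that array the adjusted p was 0.00017 (camera). Nor does it rest on Stat3, Klf4, Klf5 and Tfcp2l1, in common with the LIF list, as the 14 other members gave an adjusted p of 0.00087. No member is also in the hypoxia and glycolysis list, so this test says nothing about genes that respond to hypoxia. The naive list lost its call without uninduced array 2, in a fit with a lone uninduced array, at a median of -0.036 in place of -0.053. Its mean was 7.21 and 7.24 on the uninduced arrays and 7.14, 7.09 and 7.12 on the induced arrays. Every induced mean lay below both uninduced means, but only 4 of the 18 members had every induced array below both uninduced arrays. These means are the pattern itself, so they cannot decide whether a difference between the 2 uninduced arrays contributes to it. How much of the change that difference adds stays open. A small fall of naive genes in induced cells may be present. Its call was made at the preset correlation of 0.01 and was lost with the estimated one, at 0.016. The primed epiblast list, which had no call, also had a negative median, at -0.036, with 9 members lower and 5 higher. These lists therefore do not show a shift from the naive towards the primed state.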
